A study of Mus musculus with 24 samples.

How the data were processed

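Polyadenylated RNA was measured in 24 libraries of cardiomyocytes from 4-week-old mice. Cells were released by Langendorff perfusion, a digestion of the heart through its own vessels, and purified by fluorescence-activated sorting, per the labels' protocols. RNA was amplified as full-length cDNA with a SMART-Seq kit and made into dual-indexed libraries with Nextera XT, per the labels' protocols. Neither kit marks the strand, so overlapping and antisense genes cannot be told apart. The 4 groups hold 6 libraries each and were taken from the sample titles. Nothing in the labels says whether the 6 libraries of a group came from separate animals, so p-values measure only the spread between these libraries. The libraries of a group were checked for repeated deposits: over the 60 pairs within groups the chi-square statistic per gene lay between 6.83 and 112.16, and no pair agreed within sampling noise.

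The deposited count table holds whole-number read counts per gene for all 24 libraries, with 23337 genes and no line without a gene name. The submitters' processing notes name STAR, featureCounts and DESeq2 and the mouse genome build mm10, without versions. How reads that match several places were counted is not given in the sources used here, so genes with near-identical copies are uncertain. Among the genes named here these are the actins, the ribosomal protein genes and Ces1d. No line of the table lies on the mitochondrial chromosome, so mitochondrially encoded RNA was not analysed here. The authors also deposited 6 tables of pairwise comparisons, with log2 fold changes and their standard errors on the log2 scale, and p-values with adjusted p-values, per the file headers. Refits with DESeq2 gave the same log2 fold changes as these deposited tables within 0.001 for 100% of the genes when Ctrl 3 and DKO 1 were left out. The 22 remaining libraries are therefore used as an alternative, chosen after seeing the data.

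Counts were tested with edgeR 4.0.16 in R 4.3.3 by the quasi-likelihood test, two-sided, with TMM scaling and all 24 libraries in one fit with a coefficient per group. Genes with low counts were removed by filterByExpr with its minimum count of 10, which left 12281 genes. Benjamini-Hochberg adjustment ran over these genes and a gene was called at an adjusted p under 0.05. Every adjusted p for a gene comes from this test unless another is named. Fold changes are given as log2 ratios with their standard error, and levels as CPM (read counts scaled to the effective library size), as the group mean with the SD over 6 libraries. The 7 comparisons are the 6 pairs of groups and the interaction, (TKO minus DKO) minus (MKO minus Ctrl) on the log2 scale. These designs, the gene lists, the rule for named genes and the alternatives given below, except those added later, were fixed before the data were examined.

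The rule named Myocd, Mrtfa, Mrtfb and Srf, then the 10 largest rises and 10 largest falls among called genes in the comparisons with Ctrl, and 5 of each in the other comparisons. Such genes needed at least 10 CPM in the higher group and at least 5 of 6 libraries beyond the mean of the other group. Xist, Tsix, Y-linked genes, numbered clone names and pseudogenes were left out. Other genes on the X chromosome were kept. From each list the up to 4 members with the smallest adjusted p were named. Not every gene that the rule gives is printed, for space, and some were left out because they were withheld from this text. Called genes named for the 5 pairs of groups with calls had at least 5 of 6 libraries beyond the mean of the other group. Gene symbols are those of the deposited table, and older ones are given with the current symbol. Positions are those of the deposited table in mm10.

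The 28 gene lists cover the contractile apparatus, calcium handling, ion channels, metabolism, stress responses, matrix and markers of the cell types a sorted heart preparation could hold. Of 746 list entries, 726 matched a line of the table, and 25 lists had enough tested genes for a test. Lists share members, such as Acta2 in the MRTF-SRF, fetal and stress, and smooth muscle lists. In another list as well are 12 fetal and stress, 11 MRTF-SRF, 8 matrix and 7 fibroblast entries, so list results are not independent. Lists were tested with camera of limma 3.58.1 on voom log2 CPM with a preset correlation of 0.01, adjusted over lists and comparisons. They were tested again with an estimated correlation and with fry, which asks whether the members move one way on balance. With an estimated correlation no list passed in any comparison, and the lowest adjusted p was 0.431. List scores per library are the mean log2 CPM of the members, compared between groups by exact permutation tests, two-sided, adjusted over 150 tests.

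Tests were tried on simulated data drawn from the means, spread and library sizes of these libraries. For MKO versus Ctrl, edgeR recovered 50.7% of genes changed 1.5-fold, 86.6% of those changed 2-fold and 98.5% of those changed 4-fold, with 10.8% of calls false. For TKO versus Ctrl the shares were 41.8%, 79.1% and 98.5%, with 4.58% false. For the interaction they were 25.4%, 64.2% and 86.4%, with 4.69% false. These simulations used 12275 genes. A shift of 0.5 on the log2 scale given to the p53 response list in simulated DKO libraries was found by camera (adjusted p = 9.95e-25), by camera with an estimated correlation (4.58e-09) and by fry (5.34e-11), and 0 of 22 other lists were called. Simulated genes were drawn independently of each other. In the real libraries the estimated correlation between members reached 0.83, for oxidative phosphorylation. The trial therefore does not show how the list tests behave with correlated members.

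Alternatives were RLE size factors, no filter and a stricter filter on low counts (at least 10 CPM in 6 libraries), DESeq2 1.42.0, voom with quality weights, the replicate number as a block, inferred sex as a covariate, genes within 10 Mb of the targeted loci left out, only the groups compared in the fit, an adjusted p under 0.01 and each library left out in turn. Added after seeing the data were the 22 libraries above, the same libraries with inferred sex, and a score of non-myocyte markers as a covariate. Sex was inferred from Xist against 4 Y-linked genes and held only as a label per library. Total counts per library lay between 5.83 and 17.18 M, so that 3 counts, taken as the floor, correspond to 0.175 to 0.515 CPM. Reads without molecular identifiers are not independent molecules, and the floors cover counting error only. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.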

Results

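The data describe heart muscle cells in which 3 related transcriptional coactivators were targeted, singly or together. Myocardin (Myocd) and the myocardin-related factors Mrtfa and Mrtfb bind serum response factor (Srf) and drive genes of the actin cytoskeleton and of contraction. Newborn mice were injected on postnatal day 1 with an adeno-associated virus (AAV) and their cardiomyocytes were collected at 4 weeks. Control mice (Ctrl) carried the Cas9 nuclease in the Rosa26 locus and received a Cre virus. The group named MKO had the same genotype and received a virus with guide RNA against Myocd. The DKO group lacked Mrtfa, carried floxed Mrtfb and Cas9, and received the Cre virus. The TKO group had the DKO genotype and received the Myocd guide virus. Each group held 6 libraries. Total counts averaged 9.59 ± 1.40 M in Ctrl, 11.57 ± 1.37 in MKO, 10.18 ± 2.50 in DKO and 11.95 ± 2.64 in TKO (SD, n = 6). The shallowest library was DKO 1 with 5.83 M and the deepest TKO 3 with 17.18 M. By sex-linked transcripts, 4 of 6 Ctrl, 4 of 6 MKO, 1 of 6 DKO and 3 of 6 TKO libraries were male.

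The targeted genes were examined first in every library. Mrtfa, listed under its older symbol Mkl1 (chromosome 15, 81012281 to 81190757), lay between 4.81 and 11.33 CPM in the Ctrl libraries and between 6.39 and 11.87 CPM in MKO. It lay between 1.40 and 2.77 CPM in DKO and between 1.33 and 2.66 CPM in TKO, with no overlap with either of the other groups. Against Ctrl it fell by 1.92 ± 0.21 on the log2 scale in DKO (adjusted p = 7.56e-06) and by 1.86 ± 0.21 in TKO (adjusted p = 8e-07). Mrtfb, listed as Mkl2 (chromosome 16, 13256481 to 13417529), spanned 44.78 to 55.89 CPM in Ctrl, 44.11 to 59.19 in MKO, 26.57 to 39.31 in DKO and 27.47 to 42.52 in TKO. It fell by 0.57 ± 0.11 in DKO (adjusted p = 0.00603) and by 0.46 ± 0.11 in TKO (adjusted p = 0.0041). Counts over the whole gene include exons outside a floxed part, so this partial fall gives no measure of how many cells lost Mrtfb.

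Myocd (chromosome 11, 65176571 to 65269989) spanned 152.74 to 234.35 CPM in Ctrl, 119.79 to 187.01 in MKO, 175.38 to 242.17 in DKO and 175.22 to 323.46 in TKO. Its log2 ratio was -0.37 ± 0.13 in MKO (adjusted p = 0.717), 0.17 ± 0.13 in DKO (adjusted p = 0.686) and 0.40 ± 0.13 in TKO against Ctrl (adjusted p = 0.0437). The TKO call was lost with RLE size factors (adjusted p = 0.0504), with the replicate number as a block (0.0598) and with only the 2 groups in the fit (0.0658). It was also lost without Ctrl 1, 3, 4, 5 or 6, MKO 1, 5 or 6, DKO 4 or 5, or TKO 1, 3, 4 or 5 (adjusted p from 0.0501 to 0.133). Myocd was 0.77 ± 0.13 higher in TKO than in MKO (adjusted p = 0.000374). A small insertion or deletion made by a guide need not lower the counts of a gene, so these values do not check the editing of Myocd. Srf (chromosome 17, 46546839 to 46556162), the shared partner, averaged 81.90 ± 12.02 CPM in Ctrl, 87.62 in MKO, 65.55 in DKO and 42.83 ± 4.57 in TKO. All 6 TKO libraries, at 38.34 to 50.90 CPM, lay below the 6 Ctrl libraries, and Srf fell by 0.93 ± 0.15 (adjusted p = 6.97e-05). In DKO its log2 ratio was -0.33 ± 0.14 (adjusted p = 0.421). It was -0.52 without DKO 1 (adjusted p = 0.0165), the library with 105.26 CPM of Srf against 52.01 to 63.58 in the other 5.

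**Figure D1:**
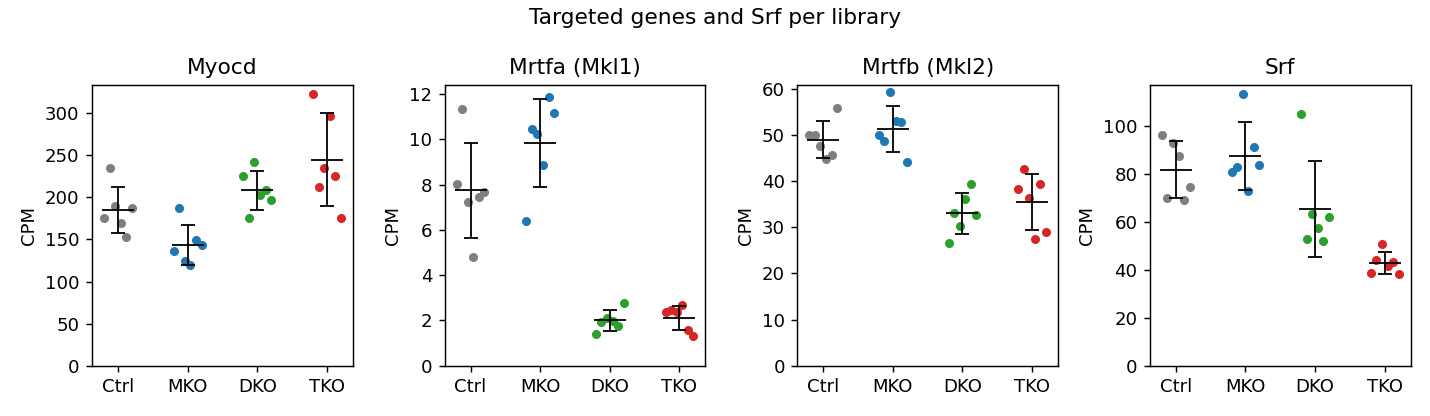
CPM (linear axis) of Myocd, Mrtfa, Mrtfb and Srf in the 24 libraries by group, with the mean and SD of 6 libraries as bars. Mrtfa does not exceed 2.77 CPM in the DKO and TKO libraries and is at least 4.81 CPM in the others, and Srf is at most 50.90 CPM in TKO and at least 69.40 CPM in Ctrl.

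The comparison of MKO with Ctrl asked what targeting Myocd alone changed. No single gene passed the threshold, while markers of cells other than cardiomyocytes stood higher in the MKO libraries. Fibroblast markers had a median log2 ratio of 0.78 over 12 genes, among them Dcn at 0.78 ± 0.29 and Dpt at 1.21 ± 0.45, which encode matrix proteins made by fibroblasts. The medians were 0.55 for 15 endothelial markers (Vwf, at 0.76 ± 0.38), 0.63 for 12 smooth muscle and pericyte markers (Rgs5, at 0.94 ± 0.39) and 1.06 for 8 leukocyte markers (C1qb, at 1.24 ± 0.35). Extracellular matrix genes had a median of 0.65 over 32 genes, and interferon response genes a median of 0.30 over 32 genes, with Bst2 at 0.93 ± 0.31. With the 22 libraries, which leave out Ctrl 3, the interferon median was 0.18 and the endothelial median 0.34. None of the genes named in this paragraph passed over all genes. Adjusted over the list alone, 5 fibroblast markers rose, and 6 leukocyte markers rose and 1 fell.

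Sarcomere genes had a median log2 ratio of -0.14 in MKO over 39 genes, with Trim55, a ubiquitin ligase of the sarcomere, at -0.27 ± 0.09 and titin (Ttn) at -0.52 ± 0.22. The medians were -0.09 for 29 calcium handling genes, -0.15 for 50 oxidative phosphorylation genes, -0.14 for 49 ribosomal protein genes and -0.14 for 15 ventricular markers. Markers of non-myocytes stood higher in the same libraries. Camera called these 11 lists, from 7.22e-11 for the matrix to 0.00931 for calcium handling. With an estimated correlation the adjusted p was 0.58 for the matrix list, 0.535 for the sarcomere and 0.847 for oxidative phosphorylation, and fry called 0 of the 25 lists. Kcnip2, a subunit of the transient outward potassium channel, was at -0.52 ± 0.16 (adjusted p = 0.698). Itgb1bp2 (melusin), a muscle protein that binds integrin, was at -0.67 ± 0.17 (adjusted p = 0.698) and was the only costamere gene lower adjusted over the list alone.

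The count of 0 genes came from edgeR, in which 762 of the 12281 genes had an unadjusted p under 0.05 against 614 expected by chance, with a smallest adjusted p of 0.414. DESeq2 called 1 gene and voom with quality weights 3, and DESeq2 on the 12 libraries of these groups alone called 32, 15 higher and 17 lower. The authors' deposited table has 15 genes with an adjusted p under 0.05 for this comparison, 8 higher and 7 lower, and lists Myocd at -0.37 ± 0.13 on the log2 scale (adjusted p = 0.418). Kcnip2 (-0.50, adjusted p = 0.00362), Itgb1bp2 (-0.62, adjusted p = 0.0188) and Myl9 (0.86, adjusted p = 0.0242) are among the 15 in the authors' deposited table.

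The comparison of DKO with Ctrl asked what the Mrtfa and Mrtfb mutations changed. It gave 78 called genes, 37 higher and 41 lower, and actin cytoskeleton genes were prominent among those that fell. Smooth muscle actin (Acta2), which is also expressed in immature cardiomyocytes, fell by 2.17 ± 0.27 on the log2 scale, from 776.60 ± 146.10 CPM in Ctrl to 173.14 CPM (adjusted p = 2.23e-05). Skeletal actin (Acta1) fell by 2.20 ± 0.49 (adjusted p = 0.0291), cytoplasmic actin (Actg1) by 1.61 ± 0.31, the myosin regulatory light chain Myl9 by 1.77 ± 0.33 and the actin-binding calponin Cnn2 by 1.10 ± 0.23. Acta1 and Acta2 were the 2 fetal and stress genes that fell, whereas 1 gene of that list fell with the 22 libraries. Of 38 tested MRTF-SRF cytoskeletal targets 7 fell and 0 rose, and adjusted over the list alone 8 fell. Wdr1, which helps cofilin disassemble actin filaments, fell by 0.64 ± 0.10, and Pdlim7, a protein of the actin-bound Z-disc, by 0.93 ± 0.17. Camera called the list at an adjusted p of 1.05e-08 and fry at 0.0323, and the adjusted p = 0.431 with an estimated correlation.

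Few other groups held called genes in DKO. Of 29 calcium handling genes 2 fell and 0 rose: the sodium-calcium exchanger Slc8a1 fell by 0.59 ± 0.12 and calsequestrin (Casq2), which stores calcium in the sarcoplasmic reticulum, by 0.36 ± 0.08. Camera called this list (adjusted p = 0.00069; adjusted p = 0.538 with an estimated correlation). Of 35 ion channel genes 2 fell, Kcne1 by 0.66 ± 0.14 and Kcnip2 by 0.76 ± 0.17, both subunits of repolarizing potassium channels. Timp2, an inhibitor of matrix metalloproteinases, fell by 0.69 ± 0.13 and was the only one of 32 matrix genes called. Ucp2, a carrier of the inner mitochondrial membrane, rose by 0.98 ± 0.23 and was the only one of 42 fatty acid oxidation genes called. Of the sarcomere and costamere genes none passed over all genes, with medians of -0.06 and -0.10 (camera 0.0192 and 0.000473; adjusted p = 0.771 and 0.634 with an estimated correlation). Glycolysis genes had a median of -0.11 with 0 called, and adjusted over the list alone 3 fell (camera 2.29e-05; adjusted p = 0.557 with an estimated correlation). Fibroblast markers had a median of 0.41 and leukocyte markers of 0.64 with 0 members called (camera 0.00255 and 0.0273, and adjusted p = 0.78 and 0.771 with an estimated correlation). Acta2 was the only one of 12 smooth muscle and pericyte markers called. Camera also called interferon response genes (median 0.17, 0.0012), endothelial markers (0.08, 0.0438) and ventricular markers (-0.12, 0.0446), with 0 members called. With an estimated correlation their adjusted p lay between 0.78 and 0.847.

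The largest rises in DKO were those of Arc (4.90 ± 0.60), a regulator of synaptic receptors that stood at 0.69 CPM in Ctrl and 20.13 CPM in DKO, and of the cytokine Il15 (1.82 ± 0.43). Gnao1, a G protein alpha subunit, rose by 1.24 ± 0.17, the receptor kinase Grk5 by 1.12 ± 0.17, Haus8 by 1.12 ± 0.19, Shisa4 by 1.11 ± 0.21, the hyaluronan receptor Cd44 by 0.96 ± 0.16, Jrk by 0.90 ± 0.15 and the transcription factor Etv5 by 0.82 ± 0.16. Among the falls outside the cytoskeleton were Rtn4r (2.64 ± 0.38, the Nogo receptor), Zfp868 (1.58 ± 0.20), Lynx1 (1.42 ± 0.17), Ocel1 (1.36 ± 0.16) and Snn (1.18 ± 0.14). Several of these genes lie near the targeted loci. Arc, Jrk and Lynx1 lie 6.34, 6.30 and 6.26 Mb from Mrtfa, and Snn, Rtn4r and Etv5 lie 2.18, 4.71 and 8.96 Mb from Mrtfb. The ribosomal protein gene Rpl3, which fell by 1.98 ± 0.24, lies 0.929 Mb from Mrtfa. Haus8, Zfp868 and Ocel1 lie together on chromosome 8, between 68.3 and 75.2 Mb. In all 30 called genes named by rule the 6 DKO libraries lay beyond the Ctrl mean. Without genes within 10 Mb of the targeted loci, 50 genes were called. With only the 2 groups in the fit there were 43, 13 higher and 30 lower, and without DKO 1 there were 124, 43 higher and 81 lower. The authors' deposited table has 235 genes with an adjusted p under 0.05, 82 higher and 153 lower.

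The comparison of TKO with Ctrl asked what targeting all 3 coactivators changed. It gave 1734 called genes, 1000 higher and 734 lower, and 392 of them differed at least 2-fold, 274 higher and 118 lower. With the 22 libraries the split was more even, 1358 higher and 1269 lower. Srf and the actin genes Acta2, Actg1 and Actc1 fell, 12 of 27 fetal and stress genes rose, and 13 of 50 oxidative phosphorylation genes and 5 of 15 ventricular markers fell. Atrial natriuretic peptide (Nppa), a marker of stressed heart muscle, rose by 2.92 ± 0.78 on the log2 scale (adjusted p = 0.0118), from 193.51 ± 133.60 CPM to 1460.09 ± 1503.26 CPM. The muscle creatine kinase Ckm fell by 1.62 ± 0.20, from 3821.85 ± 398.65 CPM to 1239.17 ± 518.97 CPM (adjusted p = 4.76e-06).

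Of 27 fetal and stress genes 12 rose and 2 fell, with a median log2 ratio of 0.73. The calcium channel Cacna1g, which is expressed in the fetal ventricle, rose by 1.02 ± 0.12, the calcineurin regulator Rcan1 by 1.09 ± 0.13 and the LIM protein Fhl1 by 1.32 ± 0.15, while Acta2 fell by 2.76 ± 0.27. Camera called the list at 0.00132 and fry at 0.0101, and the adjusted p = 0.538 with an estimated correlation. Of 38 MRTF-SRF targets 11 fell and 3 rose (camera 0.0065; adjusted p = 0.768 with an estimated correlation). Myl9 fell by 2.38 ± 0.33, Actg1 by 2.14 ± 0.31, Cnn2 by 1.77 ± 0.24 and Pdlim7 by 1.47 ± 0.18.

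Contractile and membrane genes went both ways in TKO. Of 39 sarcomere genes 6 rose and 9 fell, with cardiac actin (Actc1) falling by 1.17 ± 0.19, tropomyosin (Tpm1) by 0.72 ± 0.12 and Trim55 by 0.67 ± 0.09, while the myosin light chain kinase Mylk3 rose by 0.56 ± 0.10. Of 37 costamere and intercalated disc genes 8 rose and 1 fell. Sorbs2, an adaptor of the Z-disc, rose by 0.92 ± 0.14 and Lmo7 by 0.57 ± 0.12, and Itgb1bp2 fell by 0.98 ± 0.17. Camera called neither list (adjusted p = 0.902 and 0.168), and the sarcomere list had a median of 0.14 and a mean of -0.02. Of 35 ion channel genes 6 rose and 5 fell. Kcnip2 fell by 1.72 ± 0.17, Hcn2, a pacemaker channel, by 0.99 ± 0.15 and Kcne1 by 0.95 ± 0.14. Of 29 calcium handling genes 2 rose and 7 fell (camera 0.0336; adjusted p = 0.639 with an estimated correlation). Casq2 fell by 0.44 ± 0.08 and Tmem38a, a counter-ion channel of the sarcoplasmic reticulum, by 0.47 ± 0.14. The skeletal isoform Casq1 rose by 1.58 ± 0.40.

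Of 50 oxidative phosphorylation genes 13 fell and 0 rose, and adjusted over the list alone 15 fell. With the 22 libraries 25 fell, and 15 fatty acid oxidation genes. Sdha of complex II fell by 0.54 ± 0.10, the complex I subunits Ndufv1 and Ndufs1 by 0.53 ± 0.13 and 0.43 ± 0.10, and the ATP synthase subunit Atp5a1 by 0.42 ± 0.11. Camera called the list at 5.04e-08, and the adjusted p = 0.78 with an estimated correlation. Of 42 fatty acid oxidation genes 8 fell and 2 rose (camera 0.0113; adjusted p = 0.83 with an estimated correlation). Ppargc1b, a coactivator of mitochondrial genes, fell by 0.85 ± 0.12, Etfdh by 0.43 ± 0.10, and the trifunctional protein subunits Hadhb and Hadha by 0.48 ± 0.11 and 0.40 ± 0.09. Of 26 glycolysis genes 3 rose and 4 fell. The lactate carrier Slc16a3 rose by 1.40 ± 0.26 and Pfkp by 0.52 ± 0.09, while the insulin-regulated glucose carrier Slc2a4 fell by 0.72 ± 0.14. Of 15 ventricular markers 5 fell and 0 rose, among them Myl3 by 0.76 ± 0.19, Ttn by 0.80 ± 0.22 and Myh6 by 0.63 ± 0.18 (camera 0.00266; adjusted p = 0.557 with an estimated correlation). The mean score of these ventricular markers was 10.64 ± 0.13 in TKO and 11.03 ± 0.08 in Ctrl, with no overlap between the 6 and 6 libraries (exact p = 0.00216, the smallest possible, adjusted p = 0.054). Among markers of other cells the fibroblast marker Gsn rose by 0.48 ± 0.14, and the list medians were -0.22 for fibroblasts, -0.61 for endothelium and 0.71 for leukocytes, none called by camera with all 24 libraries. With the 22 libraries 4 endothelial markers fell (median -0.81, camera 0.000726; adjusted p = 0.809 with an estimated correlation), as did 8 of the matrix genes (camera 0.0407; adjusted p = 0.827 with an estimated correlation), against 0 and 1 with all libraries.

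Of 25 p53 response genes 7 rose and 0 fell. Eda2r, a receptor of the tumour necrosis factor family, rose by 1.36 ± 0.26, the cell cycle inhibitor Cdkn1a by 1.19 ± 0.28 and Trp53inp1 by 0.84 ± 0.22 (fry 0.0336; camera 0.22; adjusted p = 0.617 with an estimated correlation). Of 27 integrated stress response genes 3 rose and 3 fell, with the secreted stress hormone Gdf15 rising by 2.13 ± 0.50 and asparagine synthetase (Asns) falling by 1.46 ± 0.31. The largest rises were those of Kcne1l (Kcne5, a potassium channel subunit), by 5.23 ± 0.50 from 0.50 to 18.96 CPM, Lrp8 (4.33 ± 0.57), Krt80 (3.68 ± 0.48) and Gnao1 (3.13 ± 0.17), which went from 6.01 ± 0.92 to 52.60 ± 12.60 CPM. Nlrc3, Etv5, Mmp23, Cp and Cd44 rose by 2.97 ± 0.39, 2.63 ± 0.16, 2.50 ± 0.25, 2.45 ± 0.23 and 2.40 ± 0.17. Among the other large falls were those of Hrasls (Plaat1, a phospholipid-modifying enzyme), by 2.79 ± 0.83, Rtn4r by 2.70 ± 0.37, Ces1d by 2.37 ± 0.39 and Snn by 1.72 ± 0.14. Nlrc3 and Etv5 lie 9.28 and 8.96 Mb from Mrtfb. In 73 of the 79 called genes named by rule all 6 TKO libraries lay beyond the Ctrl mean, and in the others 5. Without DKO 1, a library of neither group, 2808 genes were called. The authors' deposited table has 2177 genes with an adjusted p under 0.05, 1152 higher and 1025 lower, and 1528 of the 1734 are among them. For the other comparisons the authors' deposited tables have 1519 such genes for TKO versus DKO, 3021 for TKO versus MKO and 473 for DKO versus MKO, against 784, 1639 and 97 here.

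**Figure D2:**
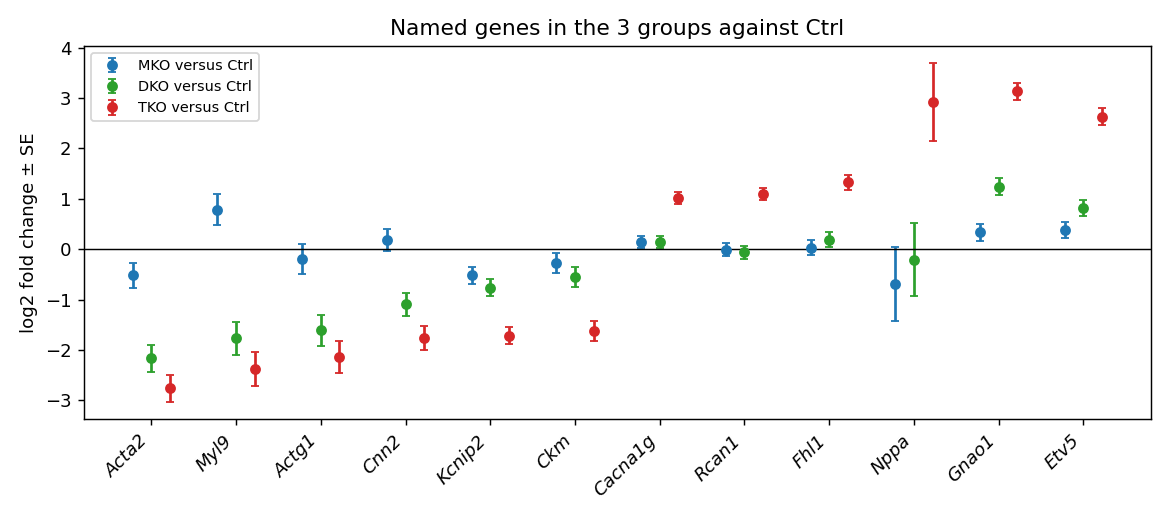
Log2 fold change against Ctrl (vertical axis) with its standard error for 12 genes in MKO, DKO and TKO, each from 6 against 6 libraries. Acta2 stands at -2.17 in DKO and -2.76 in TKO, whereas Rcan1 stands at -0.06 in DKO and 1.09 in TKO.

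The comparison of TKO with DKO asked what the Myocd guide virus changed in mice of the same Mrtf genotype. It gave 784 called genes, 511 higher and 273 lower. With the marker score of other cells as a covariate these numbers were 787 and 759, with voom 857 and 704, and with only these 12 libraries in the fit 216 and 53. Of 27 fetal and stress genes 11 rose and 0 fell, with Rcan1 at 1.16 ± 0.13, Fhl1 at 1.13 ± 0.15, Cacna1g at 0.87 ± 0.12 and the peptide hormone gene Edn3 at 3.73 ± 0.61 (camera 1.73e-05, fry 0.00597; adjusted p = 0.431 with an estimated correlation). Of 37 costamere genes 10 rose and 1 fell, with Sorbs2 rising by 0.90 ± 0.14, Ank3 by 0.59 ± 0.12 and Itgb1bp2 falling (adjusted p = 0.000676). Camera called the costamere list at 2.29e-05 and fry at 0.0407, and the adjusted p = 0.538 with an estimated correlation. DKO 1 had the lowest costamere score of its group. With the 22 libraries, which leave it out, the costamere median went from 0.24 to 0.15, with 11 rises (camera 0.000262). Of 50 oxidative phosphorylation genes 5 fell and 0 rose, Ndufv1 by 0.50 ± 0.13 and Uqcrfs1 by 0.62 ± 0.17 (camera 7.22e-11; adjusted p = 0.78 with an estimated correlation). Adjusted over the list alone 27 fell, and DKO 1 scored 10.43 for this list against 9.27 to 9.38 in the other DKO libraries. The median of the list was -0.39 and became -0.12 without DKO 1 (camera 3.16e-05), and with the 22 libraries it was -0.11 with 2 falls. Srf fell by 0.61 ± 0.14 (adjusted p = 0.0115).

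Of 38 MRTF-SRF targets 5 rose and 2 fell between DKO and TKO. Skeletal actin (Acta1) was higher in TKO by 2.57 ± 0.50, the fibronectin receptor subunit Itga5 by 0.64 ± 0.10 and the focal adhesion protein Zyx by 0.91 ± 0.15 (camera 0.826, upward, against a list median of -0.14). Slc16a3 rose by 1.41 ± 0.26, Gdf15 by 2.31 ± 0.50 and Nppa by 3.12 ± 0.79, and Ckm fell by 1.07 ± 0.20. Among the largest falls were Ces1d (2.39 ± 0.39), Stk11 (1.40 ± 0.41), Csda (Ybx3, 1.35 ± 0.37), Apold1 (1.35 ± 0.39) and the kinase Pim1 (1.31 ± 0.32). Endothelial markers had a median of -0.69 over 15 genes with 0 called (camera 0.000347, and adjusted p = 0.78 with an estimated correlation). With the 22 libraries 2 endothelial markers fell, and 7 matrix genes against 1 with all libraries (camera 1.81e-05, and 0.757 with an estimated correlation). Camera also called fatty acid oxidation (0.00456), cell cycle (0.00478), smooth muscle and pericyte (0.0397) and ventricular genes (0.0422), none with an estimated correlation. Without TKO 4 there were 495 calls.

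The comparison of TKO with MKO asked what the Mrtf mutations changed under the same Myocd guide virus. It gave 1639 called genes, 796 higher and 843 lower. Some markers of non-myocytes were lower in TKO, as were cytoskeletal genes. For the markers MKO was the group that stood apart. The mean of 4 marker scores was 3.96 in MKO, 3.18 in Ctrl and 3.13 in TKO. Against Ctrl, 0 endothelial and 0 fibroblast markers and 1 matrix gene fell in TKO with all libraries. With the 22 libraries 4 endothelial markers and 8 matrix genes fell there. Of 15 endothelial markers 6 fell and 0 rose between MKO and TKO, among them Tek by 1.41 ± 0.39, Cdh5 by 1.49 ± 0.42 and Pecam1 by 1.41 ± 0.41. Of 12 smooth muscle and pericyte markers 7 fell and 1 rose, with Acta2 falling by 2.24 ± 0.27, Vtn by 1.64 ± 0.39 and Pdgfrb by 1.71 ± 0.46 and Cspg4 rising by 0.76 ± 0.20. Of 12 fibroblast markers 3 fell, Postn, Pdgfra and Ddr2, by 1.45 ± 0.42, 1.27 ± 0.39 and 1.15 ± 0.37. Of 8 leukocyte markers 0 were called, with a median of -0.30 (camera 0.909). Adjusted over the list alone 14 endothelial, 9 smooth muscle and pericyte, 10 fibroblast and 16 matrix genes fell, and with the 22 libraries 10, 8, 9 and 19 fell over all genes. Of 32 matrix genes 11 fell and 0 rose, with Timp2 falling by 1.35 ± 0.13 and fibronectin (Fn1) by 1.67 ± 0.44. Of 38 MRTF-SRF targets 14 fell and 3 rose, and Myl9 fell by 3.16 ± 0.34. Camera called the endothelial, smooth muscle, fibroblast, matrix and MRTF-SRF lists, at 0.00069 or below, and with an estimated correlation the adjusted p lay between 0.538 for the MRTF-SRF targets and 0.78 for the matrix.

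**Figure D3:**
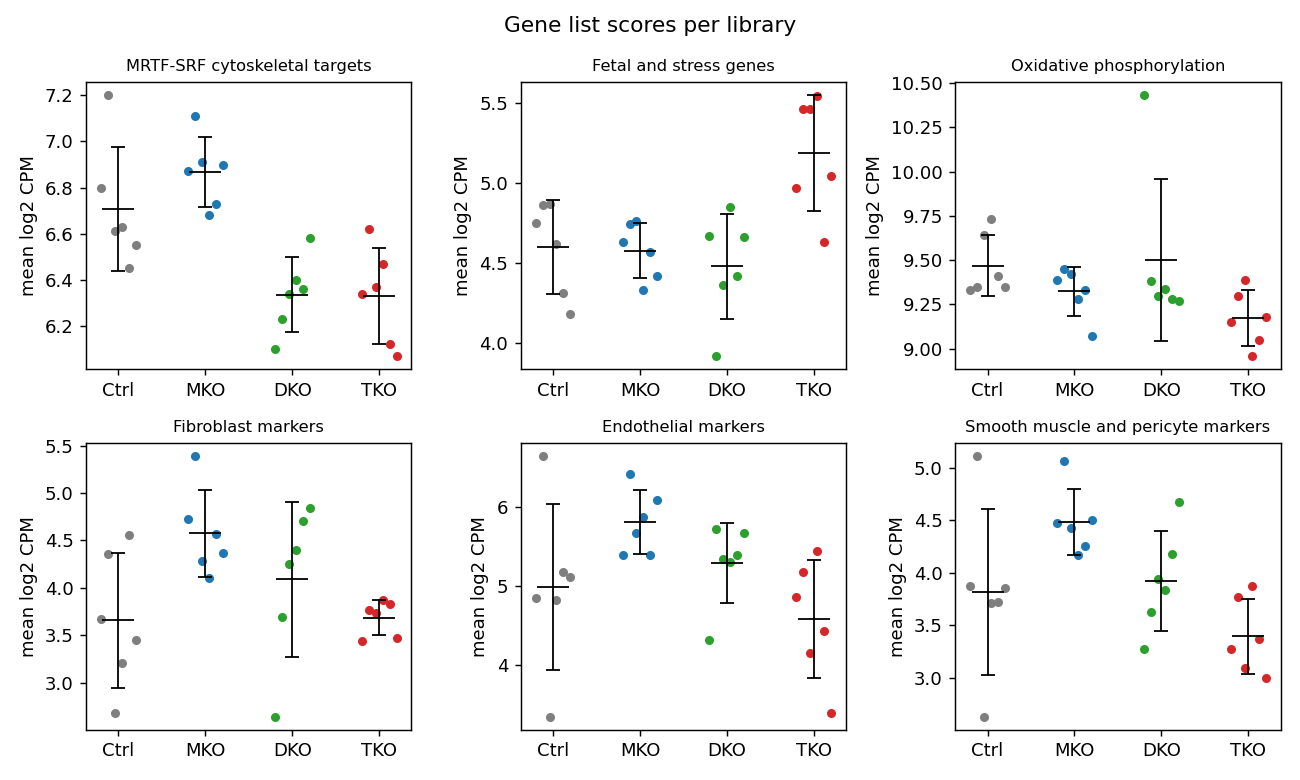
Mean log2 CPM of the members of 6 gene lists in each of the 24 libraries by group, with mean and SD of 6 libraries as bars; the axes do not start at 0. The mean smooth muscle and pericyte score is 3.82 in Ctrl, 4.48 in MKO and 3.40 in TKO, and DKO 1 stands at 10.43 for oxidative phosphorylation.

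Genes of heart muscle also differed between TKO and MKO, and with the marker score of other cells as a covariate 851 of the 1639 calls stayed among 1370. Of 27 fetal and stress genes 10 rose and 2 fell, with Edn3 rising by 5.77 ± 0.74 and Rcan1 by 1.10 ± 0.13 (camera 0.000669, fry 0.00753; adjusted p = 0.538 with an estimated correlation). Of 39 sarcomere genes 11 rose and 4 fell, Xirp2 rising by 1.11 ± 0.17 and Actc1 falling by 1.15 ± 0.19 (camera 0.047; adjusted p = 0.78 with an estimated correlation). Tnfrsf12a, the receptor for the cytokine TWEAK, rose by 1.49 ± 0.21 and the stress-linked nuclear RNA Neat1 by 1.14 ± 0.30. Neat1 belongs to the nuclear-retained RNA list, which had a median of 0.58 and was not called (camera 0.0589). Ribosomal protein genes had a median of 0.23 (camera 0.00221, and adjusted p = 0.847 with an estimated correlation). The mean of the fibroblast, endothelial, smooth muscle and leukocyte scores was 3.96 ± 0.37 in MKO and 3.13 ± 0.31 in TKO (exact permutation p = 0.00216, the smallest possible). Without DKO 1 there were 2725 calls, and with only these 12 libraries in the fit 2581.

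The comparison of DKO with MKO set the intermediate groups side by side. It gave 97 called genes, 37 higher and 60 lower, and MRTF-SRF targets were again among the falls. The split by direction turned with other models: 138 higher and 110 lower with DESeq2, 210 and 156 with inferred sex as a covariate, 273 and 257 with voom. Of the 38 targets 6 fell and 0 rose, and adjusted over the list alone 14 fell, with Myl9 falling by 2.55 ± 0.33, Acta2 by 1.64 ± 0.26, Cnn2 by 1.27 ± 0.23 and Wdr1 by 0.61 ± 0.10 (camera 1.18e-10, fry 0.00597; adjusted p = 0.431 with an estimated correlation). Rtn4r, Actg1 and Snn fell by 2.55 ± 0.38, 1.41 ± 0.30 and 1.40 ± 0.14. Titin-cap (Tcap), a Z-disc protein, rose by 0.93 ± 0.22, Ush1c by 0.91 ± 0.21, Klhl32 by 0.91 ± 0.19, Il15 by 1.88 ± 0.42 and Arc by 5.11 ± 0.59. The monocarboxylate carrier Slc16a1 fell by 0.58 ± 0.11, Kcne1 by 0.78 ± 0.14 and Timp2 by 0.89 ± 0.13. Among the other lists that camera called, medians were -0.51 for smooth muscle and pericyte markers (0.00162), -0.45 for the matrix (6.27e-06), -0.45 for endothelial markers (0.00996), -0.34 for fibroblast markers (0.0257), 0.30 for ribosomal proteins (4.87e-06) and 0.53 for nuclear-retained RNA (0.0144). With an estimated correlation their adjusted p lay between 0.657 and 0.847. Leaving genes near the targeted loci out gave 62 calls and using only these 12 libraries 48. The count was 58 without MKO 3, 63 without MKO 4, 53 without MKO 6 and 64 without DKO 2.

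The interaction asked whether the Myocd guide virus acted differently with and without the Mrtf mutations. It gave 57 called genes, 49 above and 8 below the sum of the MKO and DKO changes. With the marker score of other cells as a covariate 32 genes were called, of which 14 are among the 57. Of 27 fetal and stress genes 4 lay above that sum and 0 below, namely Rcan1 (1.16 ± 0.18), Fhl1 (1.10 ± 0.20), Acta1 (3.23 ± 0.68) and Cacna1g (0.74 ± 0.17), with camera at 1.47e-05, fry at 0.0336 and adjusted p = 0.431 with an estimated correlation. Rcan1 changed by -0.01 in MKO, -0.06 in DKO and 1.09 in TKO against Ctrl, of which only the TKO value passed. Acta1 stood at -0.66 in MKO (adjusted p = 0.792), -2.20 in DKO (adjusted p = 0.0291) and 0.37 in TKO (adjusted p = 0.658). Krt80 (3.55 ± 0.73), Ankrd45 (2 ± 0.27), the incretin receptor Gipr (1.87 ± 0.38), Gnao1 (1.56 ± 0.24), Tnfrsf12a (1.37 ± 0.29), Sorbs2 (0.86 ± 0.19) and Itga5 (0.68 ± 0.14) also lay above the sum. Gas1, a growth arrest gene, and Egflam, a matrix protein gene, lay below it, at -1.49 ± 0.22 and -1.20 ± 0.27. Of 15 named interaction results 8 lost their call when some single library was left out. Fibroblast and endothelial markers had interaction medians of -1.42 and -1.21 with 0 members called (camera 8.79e-08 and 1.18e-10; adjusted p = 0.538 with an estimated correlation for both). Adjusted over the list alone 11 fibroblast, 0 endothelial, 6 smooth muscle and pericyte and 13 matrix genes lay below the sum, and 1 smooth muscle and pericyte gene above it.

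The interaction count and its split by direction rested on single libraries and on the model. Genes above and below the sum numbered 82 and 93 with the replicate block, 203 and 559 with voom, 111 and 474 without Ctrl 2, and 253 and 318 with the 22 libraries and inferred sex. It was 585 without Ctrl 2, 201 without DKO 1, 34 without Ctrl 6 or TKO 3, 33 without MKO 5, 30 without TKO 6 and 25 without TKO 4. It was 24 without Ctrl 4, 23 without Ctrl 3, 20 without DKO 6, 18 without MKO 2, 17 without MKO 1 and 14 without DKO 2.

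**Figure D4:**
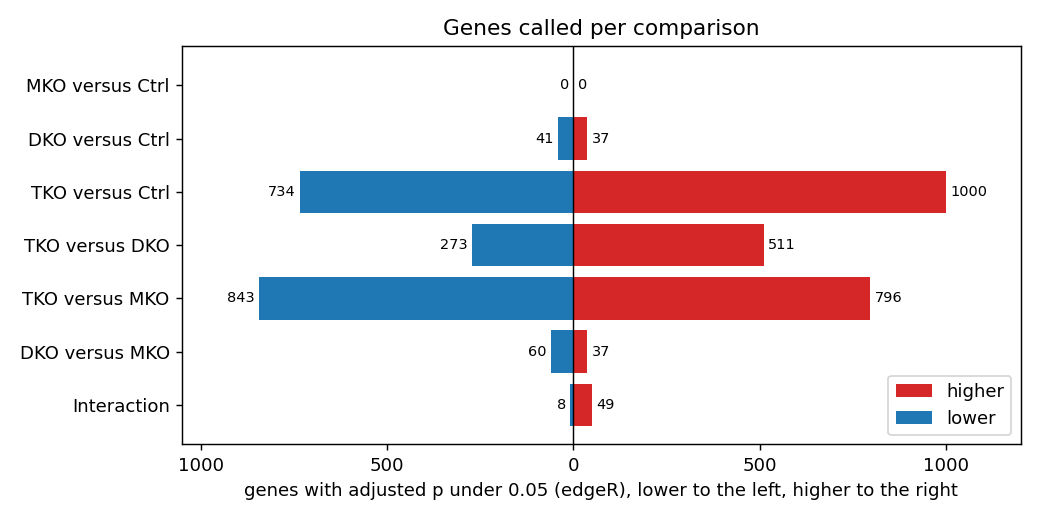
Number of genes with an adjusted p under 0.05 by edgeR (horizontal axis) in each of 7 comparisons, lower to the left and higher to the right of 0. MKO versus Ctrl has 0, DKO versus Ctrl 78 and TKO versus Ctrl 1734.

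The changes of MKO and DKO against Ctrl were set against each other to ask whether they share genes. MKO versus Ctrl had too few calls with all 24 libraries in the fit, 0 by edgeR and 1 by DESeq2, for a count of shared genes to answer this. Across the 12281 genes, which are not independent replicates, their fold changes had a Pearson correlation of 0.33. Simulated unchanged groups against the same controls gave 0.50, and the covariance was 0.0275 against a simulated 0.0281. With odd-numbered Ctrl libraries for MKO and even-numbered ones for DKO the correlation was -0.17, in the only split made. Of the 78 genes called in DKO 74 were also called in TKO with the same sign, 36 higher and 38 lower, where lists drawn independently would share 3.01 and 2.45. The covariance of these fold changes was 0.0791 against a simulated 0.0285. With the controls split 7 higher and 20 lower genes were shared, from 30 and 852 called. The comparisons DKO versus Ctrl and TKO versus MKO share no library, and 34 higher and 35 lower genes were called in both, where independent lists would share 2.40 and 2.81. Both set mice with the Mrtf mutations against mice without them. Strain DNA that differs between these lines would give shared genes as well, and the overlap does not tell it apart from the mutations. All 13 genes near Mrtfa or Mrtfb called in DKO versus Ctrl had the same sign in TKO versus Ctrl, and 2 were called in TKO versus DKO. MKO versus Ctrl and TKO versus DKO also share no library: the correlation across genes was -0.02, and 607 of the 784 genes called in TKO versus DKO had the same sign in MKO, against 58.8% of all genes and 49.9% in simulated unchanged groups.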

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

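The random splits, the thinning of counts and the fits with inferred sex or without genes near the loci were chosen before the results were seen. What the 2 fits would have to show, and the other tests of explanations in this part, were chosen only afterwards. In each group of 6 libraries a library was singled out when its gap to the nearest other exceeded 0.625 of the range of the group. Of 128 such groups 15 held one, and chance flags about 1 in 20 groups, or 6.4 of them. DKO 1 accounts for 9 of these findings. It had 13744 genes with a count (others 14745 to 15132) and 105.26 CPM of Srf (others 52.01 to 63.58). Its most abundant gene was Actc1, with 2.58% of its counts. In the other DKO libraries this gene was Myh6, with 5.64 to 7.30%. Its mean log2 CPM was 7.39 for costamere genes (7.86 to 8), 10.43 for oxidative phosphorylation (9.27 to 9.38) and 1.61 for interferon response genes (2.48 to 2.86). It was 2.86 for the matrix (4.61 to 5.31), 4.32 for endothelial markers (5.31 to 5.73) and 11.36 for ventricular markers (10.75 to 10.87).

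Other libraries far from their group were TKO 3 with a total of 17.18 M counts (others 10.21 to 11.68), Ctrl 6 with a costamere score of 8.11 (7.93 to 7.99) and TKO 4 with a cell cycle score of 1.70 (2.71 to 3.27). MKO 2 scored 5.90 for the matrix (4.92 to 5.24) and 5.06 for smooth muscle and pericyte markers (4.17 to 4.50), and TKO 6 scored 5.08 for nuclear-retained RNA (6.08 to 6.66). The interaction test between the Myocd guide virus and the Mrtf mutations called 57 genes. Of these, 14 stayed called with the marker score of other cells as a covariate. Among the named ones the difference in log2 was 3.55 for Krt80, 3.23 for Acta1, 2 for Ankrd45, 1.87 for Gipr, 1.56 for Gnao1, -1.49 for Gas1 and -1.20 for Egflam. The count ran from 14 to 585 with single libraries left out. Editing of Myocd was not measured, so unequal editing between the lines was not tested as a source of these differences.

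Chance was tested with 100 splits of the libraries per comparison, the real one included. For 6 comparisons 1 split of the 100, the real one, gave as many calls, so few random groupings of these libraries reach their counts. Splits that mix groups with a real difference widen the spread, which lowers their counts. In the interaction TKO libraries are mixed with DKO libraries in this way, so the low counts of its other splits were partly built in. Animals shared within a group, which the labels leave open, are not addressed by the splits. The real count and the highest other were 78 and 7 for DKO versus Ctrl, 1734 and 784 for TKO versus Ctrl and 784 and 141 for TKO versus DKO. They were 1639 and 10 for TKO versus MKO, 97 and 6 for DKO versus MKO and 57 and 1 for the interaction. For MKO versus Ctrl the real count and the highest other were both 0, which every one of the 100 splits reaches, so the splits say nothing about chance there.

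Genes called in DKO versus Ctrl lay near the targeted loci more often than elsewhere: 13 of 383 genes within 10 Mb of Mrtfa or Mrtfb (3.39%) against 63 of 11896 others (0.53%, Fisher p = 5.55e-07). A window on chromosome 8 away from these loci held 9 called genes, where 10000 random draws reached at most 7 (permutation p = 1e-04, the smallest possible). Strain DNA carried with the mutant alleles, or differing elsewhere between the lines, could account for these genes, and an effect of the mutations on them remains open. It was not tested for the 54 genes outside the window and the loci. With genes within 10 Mb of Mrtfa, Mrtfb, Myocd or Rosa26 left out, 50 genes were called, above the 7 of other splits. That fit kept the genes of the window, and the splits mix the lines as well as the mutations. The count of 50 therefore does not tell strain DNA apart from the mutations. With inferred sex in the model 74 of the 78 stayed called, so the larger share of females does not account for most of the list. The only male DKO library was DKO 1, so within that group sex cannot be told apart from this outlying library.

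TKO versus Ctrl gave 1734 calls and MKO versus Ctrl 0, although both groups received the Myocd guide virus. With libraries thinned to 5830185 counts TKO versus Ctrl still gave 1477 calls, above the 784 of other splits, and with the marker score of other cells as a covariate all 1734 stayed called, where the score differed little between the groups (3.13 in TKO, 3.18 in Ctrl) with Ctrl 3 included. Ctrl 3 is the lowest Ctrl library for this score, and no fit used the score without it. A score of genes that differ between TKO and DKO was higher by 0.22 in MKO than in Ctrl, with all 6 MKO libraries above every Ctrl library (exact p = 0.00216, the smallest possible). Adjusted for the marker score the difference was 0.12 (exact p = 0.113). The slope of this adjustment, 0.13 within groups, leaned on DKO 1, which scored -0.78 with an endothelial score of 4.32. No slope was fitted without DKO 1. Ctrl 2 and Ctrl 3, with endothelial scores of 6.65 and 3.35, both scored -0.23. The mean marker score was lower in TKO (3.13) than in DKO (3.52), but higher in MKO (3.96) than in Ctrl (3.18). The adjustment therefore does not decide between a small effect of the virus in MKO and RNA of other cells. Editing of Myocd was not measured, and a lower rate of editing in MKO and compensation by the Mrtf genes both remain untested explanations.

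Markers of other cell types were higher in MKO than in Ctrl, and the mean of the fibroblast, endothelial, smooth muscle and leukocyte scores differed by 0.78 (exact p = 0.0303). The 4 differences lay within 0.25 of each other, less than the mean SD of 0.61 between libraries. More cells other than cardiomyocytes, or more of their RNA, in the sorted MKO samples could give such a pattern. Without Ctrl 3 the difference was 0.55 (exact p = 0.0649). A response of these cells to the targeting of Myocd in cardiomyocytes was not tested and stays open.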

How the results depend on the processing

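The 22 libraries, the marker score and the lists without DKO 1 were chosen after seeing the data, and the other alternatives before. For 301 results of named genes, 10214 combinations with an alternative kept direction and side of the threshold. The call was lost in 774 and gained in 21, and 12 changed sign, all of these for Srf or Rcan1 where neither was called. Over single libraries left out, some fit lost the call for 8 of 15 named interaction results. The same held for 28 of 80 in TKO versus MKO, 19 of 56 in TKO versus DKO and 5 of 20 in DKO versus MKO. It held for 7 of 33 in DKO versus Ctrl and 5 of 80 in TKO versus Ctrl. RLE size factors, no filter, the stricter filter and leaving genes near the loci out kept the counts within 1.5-fold, except that leaving those genes out gave 50 calls for DKO versus Ctrl and 62 for DKO versus MKO, where fewer genes were tested. In the order MKO, DKO and TKO versus Ctrl, TKO versus DKO, TKO versus MKO, DKO versus MKO and interaction, the counts were 0, 78, 1734, 784, 1639, 97 and 57. Values beyond 1.5-fold follow, and the cause was not tested unless named. DESeq2 gave 1 for MKO versus Ctrl, 167 for DKO versus Ctrl, 1179 for TKO versus DKO, 248 for DKO versus MKO and 191 for the interaction. Voom with quality weights gave 3, 313, 2644, 1561, 3202, 530 and 762. Inferred sex gave 187 for DKO versus Ctrl, 1233 for TKO versus DKO, 366 for DKO versus MKO and 99 for the interaction. Only the groups compared gave 43, 269, 2581 and 48 for DKO versus Ctrl, TKO versus DKO, TKO versus MKO and DKO versus MKO; it was not run for the interaction, which needs all 4 groups. The 22 libraries gave 2627 for TKO versus Ctrl, 1239 for TKO versus DKO, 2892 for TKO versus MKO and 130 for the interaction, and with inferred sex 205, 2791, 1851, 2988, 349 and 571 for all but MKO versus Ctrl. The marker score gave 1546 for TKO versus DKO and 32 for the interaction. An adjusted p under 0.01 left 50, 922, 314, 647, 40 and 12.

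Leaving out each library in turn gave 0 to 1 (without Ctrl 2) for MKO versus Ctrl, 55 to 124 (without DKO 1) for DKO versus Ctrl, 1403 to 2808 (without DKO 1) for TKO versus Ctrl and 495 (without TKO 4) to 1100 for TKO versus DKO. It gave 1184 to 2725 (without DKO 1) for TKO versus MKO, 53 (without MKO 6) to 128 for DKO versus MKO and 14 (without DKO 2) to 585 (without Ctrl 2) for the interaction. DKO versus MKO also moved to 58 without MKO 3, 63 without MKO 4 and 64 without DKO 2. The interaction also moved to 23 without Ctrl 3, 24 without Ctrl 4, 34 without Ctrl 6, 17 without MKO 1, 18 without MKO 2, 33 without MKO 5, 201 without DKO 1, 20 without DKO 6, 34 without TKO 3, 25 without TKO 4 and 30 without TKO 6.

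Camera called 11, 10, 7, 8, 11, 11 and 12 lists in the same order. With an estimated correlation it called 0, 0, 0, 0, 0, 0 and 0, and fry called 0, 1, 2, 2, 3, 1 and 1. Oxidative phosphorylation in DKO versus MKO turned from 0.26 to -0.02 without DKO 1 (adjusted p = 0.709) and to -0.02 with the 22 libraries (0.735), and in the interaction from -0.25 to 0.02 without DKO 1 (0.909). With the 22 libraries oxidative phosphorylation in DKO versus Ctrl turned from 0.12 to -0.15 and gained a call (camera 0.76 and 3.21e-08), and fatty acid oxidation went from 0.01 to -0.11 (0.856 and 0.00304); with an estimated correlation neither passed. Fatty acid oxidation and ventricular markers in TKO versus DKO lost their call without DKO 1 (adjusted p = 0.0887 and 0.276). Srf in MKO versus Ctrl turned from 0.10 to -0.01 without MKO 3 (up to 0.14, without Ctrl 1), never past the threshold. Rcan1, near 0 and not called in MKO and DKO versus Ctrl, changed sign as well. In MKO it went from -0.01 to 0.05 with voom, 0 with the replicate block, 0.06 with the 22 libraries, 0.08 with these and sex, and 0.15 with the marker score, and ranged from -0.06 to 0.07 (without Ctrl 3) over single libraries left out. It was 0.03 without Ctrl 4 and 0.01 without MKO 4. In DKO it went from -0.06 to 0.01 with the 22 libraries and 0.02 with the marker score, and ranged from -0.11 to 0.02 (without Ctrl 3). The correlation of the MKO and DKO fold changes moved from 0.33 to -0.17 with the controls split, which removes the shared controls.

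Libraries with the same number in different groups are not paired in the labels. Of 36 such pairs 14 had residuals correlated above 0.1 (-0.218 to 0.642), and in 13 of 72 combinations a library correlated best with its own number. The number as a block moved the interaction to 175 calls and changed no other count beyond 1.5-fold. Thinned to 5830185 counts, the comparisons gave 0, 72, 1477, 684, 1317, 79 and 39 calls.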

Other observations

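The relations between marker scores and the list of genes on chromosome 8 in this part were chosen after the results were seen. Of 37 cell cycle genes 2 fell and 0 rose in TKO versus Ctrl, the mitotic gene Cenpf by 0.95 ± 0.20 and the replication licensing gene Cdc6 by 1.46 ± 0.49 (camera 0.00138; adjusted p = 0.847 with an estimated correlation), and the list score did not pass (exact p = 0.104). TKO 4 had the lowest score of its group for this list. Of 23 immediate early genes Myc and Jund rose, by 1.15 ± 0.26 and 0.58 ± 0.15, and Ier2 fell by 0.72 ± 0.24. The heme oxygenase gene Hmox1 rose by 1.47 ± 0.32, and Egln3, an oxygen-sensing hydroxylase, fell by 0.86 ± 0.20. The interferon-induced gene Ifit1 rose by 1.79 ± 0.46 at a low level, from 0.77 to 2.71 CPM. Neat1, a nuclear RNA, rose by 1.09 ± 0.30, from 776.05 to 1650.58 CPM.

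The 9 genes of the window on chromosome 8 that were called in DKO versus Ctrl had the same sign in TKO versus Ctrl. They are Sh2d4a at 0.73 and Haus8 at 1.12, and, lower in DKO, Zfp868 at -1.58, Mau2 at -0.46, Nr2c2ap at -1.94, Rfxank at -0.64, Ocel1 at -1.36, Abhd8 at -0.62 and Rasd2 at -1.63.

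Scores of cell type markers were correlated over the 24 libraries after the group means were removed, as a family of 10 relations. Endothelial and smooth muscle scores had r = 0.88 (rho = 0.71, permutation p = 1e-05, adjusted p = 5e-05), and r = 0.73 without the 2 farthest libraries. Fibroblast and leukocyte scores had r = 0.79 (rho = 0.87, permutation p = 1e-05, adjusted p = 5e-05), and r = 0.79 without the 2 farthest. Fibroblast and ventricular scores had r = -0.59 (rho = -0.44, permutation p = 0.0035, adjusted p = 0.007), and r = -0.26 without the 2 farthest. Ventricular scores had r = -0.38 with endothelial, -0.39 with smooth muscle and -0.19 with leukocyte scores (adjusted permutation p = 0.09, 0.09 and 0.38). Endothelial scores had r = 0.34 with leukocyte and 0.62 with fibroblast scores (0.11 and 0.0045). Smooth muscle scores had r = 0.75 with fibroblast and 0.55 with leukocyte scores (2e-04 and 0.01).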
